A study of Homo sapiens with 35 samples.

How the data were processed

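The series profiled miRNAs in RNA from formalin-fixed, paraffin-embedded biopsies of primary cutaneous melanoma, 19 with and 16 without ulceration, grouped by the tissue description of each sample. An mRNA assay that belongs to the study is not analysed here. Per the labels' protocols, total nucleic acid was isolated with a kit for fixed tissue and each nCounter cartridge lane received 100 ng of RNA, with DNA tags ligated to the miRNAs. The deposited values are raw whole-number counts per probe, with no normalization and no background subtraction visible in them, since totals differ between samples and negative control probes stand above 0. The counting software, and whether the assay's own correction factors for some probes were applied, are not given in the sources used here. The table holds 798 miRNA probes, 8 negative, 6 positive and 6 ligation controls, 5 probes for non-human miRNAs and 5 mRNA probes. Only the miRNA probes entered library sizes and tests. Some probes read more than 1 miRNA of near-identical sequence, and these are named jointly. Names of mature miRNAs are those of the table.

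A pair of columns from opposite groups was identical at all 828 probes. The planned fit used all 35 columns, but such a library cannot belong to both groups, so the comparison was made on 33 samples, 18 ulcerated and 15 non-ulcerated, and the count of calls over 35 columns is printed beside it. Sample titles carry patient numbers, and 4 of these stood in both groups among the 33 samples. Whether they mark the same patients was not settled, and the main fit treats the samples as independent. Nothing in the labels says that 2 samples are repeats of 1 lesion, and p-values measure the spread between these samples.

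Background in each sample was the mean plus 2 SD of its negative controls. miRNAs above it in at least 16 samples were tested, which kept 166. The limit of 16 was the size of the smaller group among all 35 columns and was kept, although that group held 15 samples here. A miRNA above background in non-ulcerated samples alone could therefore not be tested, while one above it in ulcerated samples alone could. Counts were normalized with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, in R 4.3.3) for an effect of group, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are log2 CPM with a prior count of 2. Fold changes come from the model and need not equal the difference of mean log2 CPM. Before the data were examined, 20 miRNA lists, 19 single miRNAs and the tests were fixed. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it. The miRNAs named are those past the threshold, the ones of smallest p in each direction up to 10, the 19 fixed miRNAs, and up to 4 members of highest level in each list. Others were chosen after their values were seen and are given in the closing part. Single measures such as total counts were compared with two-sided permutation tests of 100000 resamples, adjusted over 7 measures.

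The geometric mean of the positive controls split the samples into 3 levels, below 450, between, and above 720 counts, with 19, 6 and 8 samples. The median background was 18.5, 19.3 and 81.9 counts. The labels give no run or date, so these levels are taken as technical runs from the data. The first 3 principal components of log2 CPM held 25.8%, 15.5% and 12.6% of the variance. Group explained 8.70% of the first and the control level 18.8%.

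Depth was 31048 to 558458 miRNA counts per sample. The biological coefficient of variation was 67.5%, and the median half-width of the 95% confidence interval of a log2 fold change was 0.59. The edgeR test was tested on simulated data with the means, dispersions and library sizes of the 166 miRNAs in this comparison: with 40 miRNAs changed in each of 20 datasets, it recovered 67.8% of changes of 2-fold and 98% of changes of 4-fold, and 4.49% of its calls were false. The simulation drew each miRNA independently and held no effect of the positive control level. Its rates therefore need not hold for these samples, in which miRNAs vary together.

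Other settings fixed in advance were no filter, a mean count of at least 100, DESeq2 1.42.0 with its size factors, centring on the 100 highest miRNAs, the patient number as a random block (limma-voom), a robust variance model, sample quality weights, leaving out the 3 samples of lowest total, a Wilcoxon test, and other thresholds. Settings for the shared library, the control level, background subtraction, limma-voom without a block, the dominant probe and leaving out each sample were chosen after seeing the data. A gene table of the assembly GRCh38.p14 was used only for the chromosome of miRNA genes: 140 tested miRNAs had genes on 1 chromosome, 25 on several, and 1 was not matched.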

Results

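Small RNA levels were measured in formalin-fixed, paraffin-embedded biopsies of primary cutaneous melanoma with and without ulceration, the loss of the epidermis over the tumour. The assay was a NanoString nCounter panel, in which each microRNA (miRNA) is ligated to a DNA tag and counted through a fluorescent barcode. The table held 35 samples, 19 ulcerated and 16 non-ulcerated. A pair of columns, 1 from each group, held identical values for all 828 probes, so 1 library stood under both labels and its group could not be settled. Both columns were left out, which left 18 ulcerated and 15 non-ulcerated samples. Total miRNA counts ran from 31048 to 558458 per sample, and 109 to 348 of the 798 miRNA probes lay above background. A single probe that reads miR-4454 together with miR-7975 took 50.5% ± 15.9 (SD, n = 33) of the counts. The log2 total was 17.45 ± 1.09 (SD, n = 18) in ulcerated and 17.36 ± 1.28 (SD, n = 15) in non-ulcerated samples. This difference was not past the threshold (two-sided permutation test, p = 0.838), and 7 measures of depth and of control probes all had an adjusted p of 0.977.

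The comparison asked which miRNAs differ between ulcerated and non-ulcerated melanoma. Of 166 miRNAs tested, 3 passed the threshold, 1 higher and 2 lower in ulcerated lesions. miR-196b-5p, encoded within a HOX gene cluster, was 3.02-fold higher (log2 fold change 1.59, SE 0.39, edgeR adjusted p = 0.0139), at 8.22 ± 1.10 log2 CPM (counts scaled to library size; SD, n = 18) against 6.85 ± 1.05 (SD, n = 15). miR-4286 was 4.87-fold lower (log2 fold change -2.29, SE 0.56, edgeR adjusted p = 0.0139), at 10.30 ± 1.24 (SD, n = 18) against 12.00 ± 2.19 log2 CPM (SD, n = 15). miR-218-5p, encoded in introns of the SLIT genes, was 2.52-fold lower (log2 fold change -1.33, SE 0.29, edgeR adjusted p = 0.00776), at 7.36 ± 0.70 (SD, n = 18) against 8.56 ± 0.90 log2 CPM (SD, n = 15). The level of miR-196b-5p was above the non-ulcerated median in 16 of 18 ulcerated samples, that of miR-4286 in 2 and that of miR-218-5p in 1. miR-196b-5p and miR-218-5p were close to the detection limit: the former exceeded background in 13 of 18 ulcerated and 3 of 15 non-ulcerated samples, the latter in 10 of 18 and 12 of 15. With all 35 columns kept as labelled, 5 of 171 miRNAs passed, and a Wilcoxon rank-sum test called 0 of 166 at the same threshold, with 13 at an unadjusted p under 0.05.

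**Figure D1:**
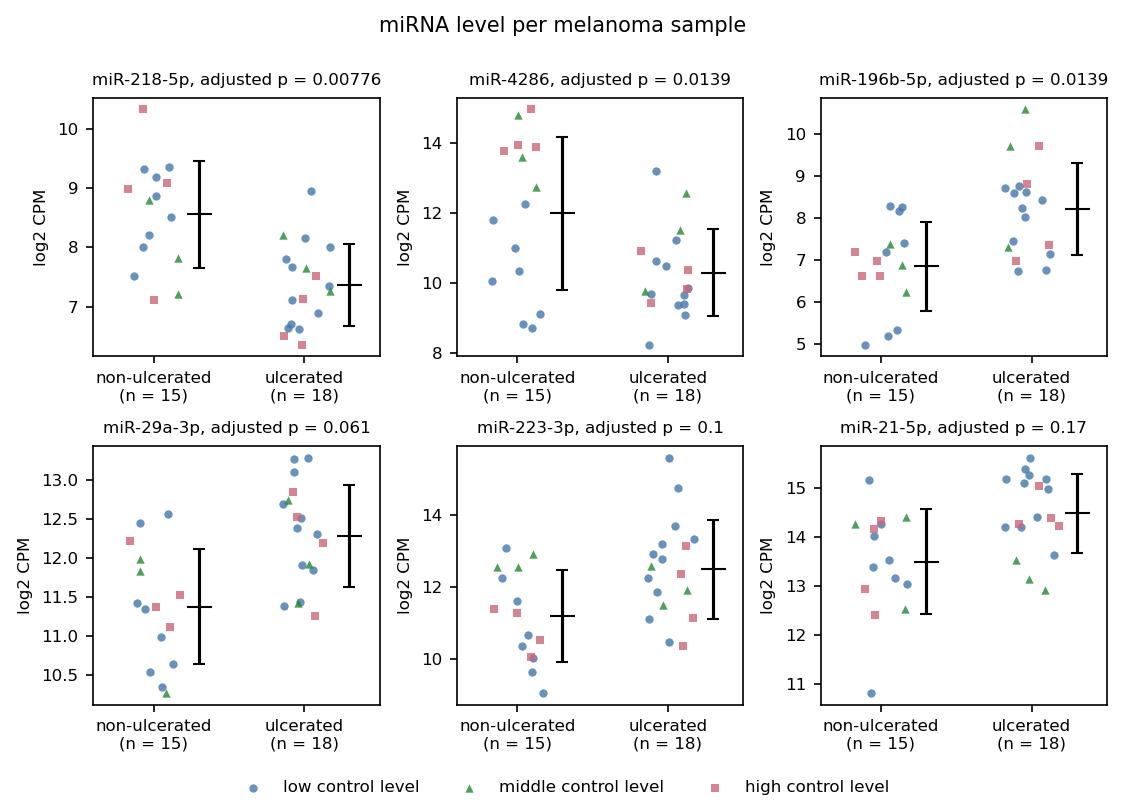
Level of 6 miRNAs in each of 33 melanoma samples, in log2 CPM on the vertical axis, with non-ulcerated samples (n = 15) on the left and ulcerated samples (n = 18) on the right of each panel. Points are samples, coloured and shaped by the level of the positive control probes, bars give the mean and SD, and the adjusted p above each panel is edgeR's. miR-196b-5p averaged 8.22 in ulcerated against 6.85 in non-ulcerated samples, and miR-4286 averaged 10.30 against 12.00.

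The miRNAs next in order of p did not pass. miR-29a-3p, of a family known to repress collagen genes, had a log2 fold change of 0.87 (SE 0.25, edgeR adjusted p = 0.061) and lay above the non-ulcerated median in 17 of 18 ulcerated samples. miR-223-3p, abundant in granulocytes and monocytes, was 2.83-fold higher by its estimate, with a log2 fold change between 0.54 and 2.46 (95% confidence interval, SE 0.47, edgeR adjusted p = 0.10). miR-29b-3p had 0.83 (SE 0.27, edgeR adjusted p = 0.106), and miR-21-5p, an abundant miRNA often raised in tumours and inflamed tissue, had 0.86 (SE 0.30, edgeR adjusted p = 0.170). On the higher side miR-185-5p at 0.64, miR-25-3p at 0.64, miR-106b-5p at 0.47, miR-148a-3p at 0.48 and let-7i-5p at 0.42 followed. On the lower side were miR-4488 at -1.31, miR-1285-5p at -1.03, miR-1915-3p at -0.72, miR-378i at -0.71, miR-199a-5p at -0.70, miR-379-5p at -0.62, miR-19a-3p at -0.60 and miR-362-5p at -0.43. Leaving out single samples moved miR-1285-5p between -1.24 and -0.60 and miR-185-5p between 0.37 and 0.84, and neither passed in any such fit. In all, 15 miRNAs had an unadjusted p under 0.05, 8 higher and 7 lower, where 8.3 would be reached by chance. Among 15 tested miRNAs of 19 named one by one before the data were examined, 0 passed over all miRNAs (edgeR). Only miR-223-3p passed when adjusted over the list alone (edgeR adjusted p = 0.0453). The other 4 were too rarely above background to be tested: miR-211-5p, the miRNA of the melanocyte gene TRPM1, exceeded it in 2 of 18 ulcerated and 1 of 15 non-ulcerated samples, miR-204-5p in 7 and 6, miR-210-3p in 6 and 4, and miR-31-5p in 2 and 2.

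The samples fell into 3 separate levels of the positive control probes, a feature of the assay and not of the tissue: 11 ulcerated and 8 non-ulcerated samples at the low level, 3 and 3 at the middle, 4 and 4 at the high. The log2 fold change of miR-4286 was -0.01 at the low, -2.27 at the middle and -3.99 at the high level, and with the control level as a block it was -1.37, no longer past the threshold (edgeR adjusted p = 0.389). miR-218-5p had -1.16, -0.18 and -2.45 in the same order, and -1.32 with the block (edgeR adjusted p = 0.0214). miR-196b-5p had 0.91, 2.98 and 1.86, and 1.48 with the block (edgeR adjusted p = 0.0457). For miR-29a-3p the values were 0.97, 0.63 and 0.71, for miR-29b-3p 1.41, 0.34 and 0.33, for miR-223-3p 2.26, -0.55 and 1.30, and for miR-21-5p 1.12, -0.70 and 0.85.

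**Figure D2:**
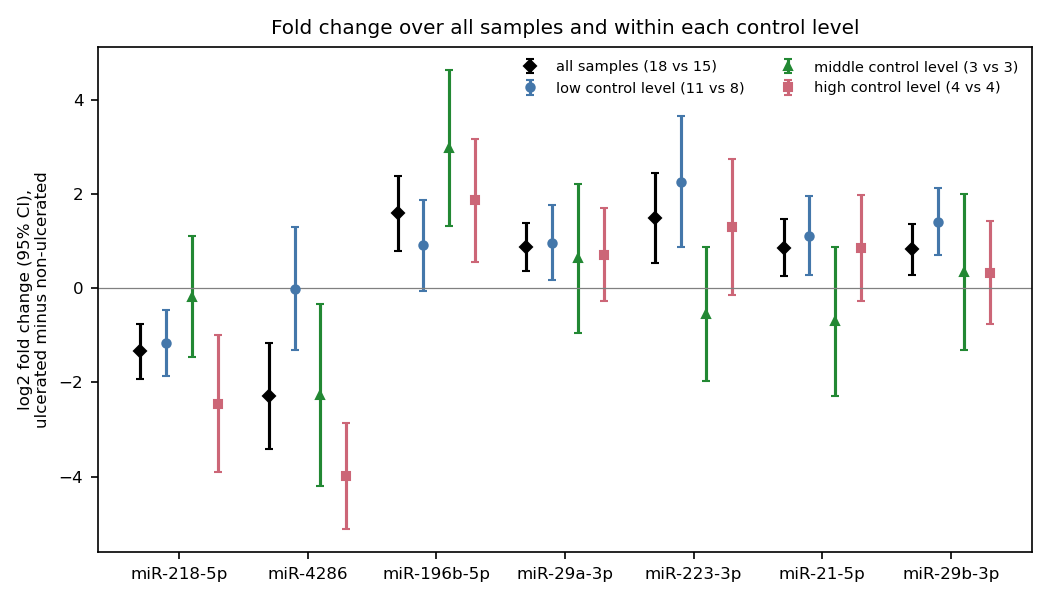
Log2 fold change, ulcerated minus non-ulcerated, with its 95% confidence interval from edgeR on the vertical axis for 7 miRNAs, over all 33 samples (black diamonds) and within the samples of the low, middle and high level of the positive control probes. miR-4286 was at -0.01 at the low level and -3.99 at the high level.

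miRNAs of wound repair and inflammation passed as higher as a list in ulcerated lesions (camera adjusted p = 0.0258), as did miRNAs of myeloid cells (camera adjusted p = 0.0258). Neither call held with an estimated correlation among members: the adjusted p = 0.145 with an estimated correlation for each. Of 6 tested wound and inflammation miRNAs, 5 had a positive fold change, and 0 passed alone over all miRNAs (edgeR). Adjusted over the list alone, 2 passed, miR-223-3p and miR-21-5p. The inflammation miRNAs miR-146a-5p at 0.72 (SE 0.47) and miR-155-5p at 0.55 (SE 0.40) did not pass. All 3 tested myeloid miRNAs were positive, with miR-142-3p at 0.41 (SE 0.32) and miR-582-5p at 0.64 (SE 0.53) beside miR-223-3p. miR-223-3p belongs to both lists. Within the low, middle and high control level the mean log2 fold change was 1.04, -0.11 and 0.27 for the wound list and 0.98, -0.16 and 1.30 for the myeloid list, and with the level as a block it was 0.62 and 0.79. With each sample left out in turn the wound list passed in all 33 fits and the myeloid list in 31. With sample quality weights neither passed (camera adjusted p = 0.0730 and 0.114), nor did the myeloid list with a mean count of at least 100 as the filter (camera adjusted p = 0.0602). The list of leukocyte miRNAs as a whole did not pass (camera adjusted p = 0.198). Without the filter on background it passed as higher with 9 members (camera adjusted p = 0.00753; adjusted p = 0.329 with an estimated correlation), and it also passed within the low control level (camera adjusted p = 0.0399). The lymphocyte list had a median of -0.05 (camera adjusted p = 0.711), with miR-150-5p at -0.05 (SE 0.41), miR-342-3p at -0.12 (SE 0.25) and miR-181a-5p at -0.03 (SE 0.27).

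miRNAs of fibroblasts and smooth muscle passed as lower as a list (camera adjusted p = 0.0258). The call was lost at an adjusted p = 0.693 with an estimated correlation. All 8 tested members had a negative fold change, among them miR-199a-5p at -0.70 (SE 0.31), miR-125b-5p at -0.55 (SE 0.31), the probe for miR-199a-3p and miR-199b-3p at -0.41 (SE 0.28) and miR-145-5p at -0.38 (SE 0.40), and 0 passed alone (edgeR). With each sample left out in turn the list mean ran from -0.58 to -0.23, and the list passed in 28 of 33 such fits (camera adjusted p up to 0.188). It did not pass without the filter on background, at a mean of -0.28 (camera adjusted p = 0.484), with sample quality weights (camera adjusted p = 0.0730) or with the shared library counted as ulcerated (camera adjusted p = 0.0507). Its mean log2 fold change was -0.43, -0.93 and -0.92 within the low, middle and high control level and -0.58 with the level as a block. The middle value rested on miR-143-3p, at -5.94 there (edgeR adjusted p = 0.000426) and -0.24 over all samples. Without it the mean of the other 7 was -0.50, -0.22 and -0.97 by level and -0.47 over all samples. The miR-29 family passed as higher as a list (camera adjusted p = 0.0258; adjusted p = 0.198 with an estimated correlation), with miR-29a-3p and miR-29b-3p past the threshold adjusted over the list alone and miR-29c-3p at -0.29 (SE 0.18). The family mean was 0.74, 0.13 and 0.25 within the low, middle and high level and 0.51 with the level as a block, and the list passed in 28 of 33 fits that each left out 1 sample. It did not pass with sample quality weights (camera adjusted p = 0.114), a mean count of at least 100 (camera adjusted p = 0.0602), all 35 columns (camera adjusted p = 0.0527), the shared library as ulcerated (camera adjusted p = 0.0507) or background subtracted (camera adjusted p = 0.0849).

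The melanocyte lineage list, which here holds 9 members of the X-linked cluster around miR-506 and miR-514, passed as higher (camera adjusted p = 0.0408; adjusted p = 0.734 with an estimated correlation). Its mean log2 fold change was 0.01 and its median -0.02, so median and test differed in sign. In the model 4 members were positive and 5 negative, while every tested member had a higher mean log2 CPM in ulcerated samples. The size depended on the fit: the mean was -0.06 under the size factors of DESeq2, 0.71 in limma-voom (camera adjusted p = 0.0212) and 0.95 with sample quality weights (camera adjusted p = 0.00733). Leaving out each sample in turn gave means from -0.10 to 0.41, and the list passed in 15 of 33 such fits. The most abundant member, miR-514a-3p, had -0.02 (SE 0.56). Its mean was 11.56 ± 1.26 log2 CPM (SD, n = 18) in ulcerated and 10.39 ± 2.50 (SD, n = 15) in non-ulcerated samples, so model and mean level went apart. Within the low, middle and high control level the list mean was -0.22, -0.61 and 1.20, and with the level as a block it was 0.07. The epithelial and keratinocyte list did not pass (camera adjusted p = 0.212). miR-205-5p, abundant in keratinocytes, had 0.02 with a 95% confidence interval from -0.89 to 0.93, and miR-203a-3p had 0.21 with an interval from -0.75 to 1.16. miR-200b-3p had -0.85 (SE 0.44), miR-200a-3p -0.71 (SE 0.36) and miR-200c-3p -0.45 (SE 0.45).

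The remaining lists did not pass. All 6 tested miRNAs of the imprinted cluster on 14q32 were negative (camera adjusted p = 0.244), from -0.96 for miR-494-3p (SE 1.02) to -0.06 for miR-539-5p (SE 0.31). The adjusted p from camera was 0.405 for the let-7 family, 0.469 for the miR-17-92 family, 0.528 for endothelial miRNAs, 0.613 for the miR-30 family and 0.692 for erythrocyte miRNAs. The endothelial miR-126-3p had 0.35 (SE 0.30). The red cell miRNA miR-451a had an estimate below 0 with a 95% confidence interval from -2.14 to 0.13, and miR-363-3p had 0.93 (SE 0.53), so members of that list went both ways. Leaving out single samples moved miR-363-3p between 0.68 and 1.79, and it passed in 1 of 33 such fits (edgeR adjusted p = 0.0271). Too few members were measurable in the lists for hypoxia (2), miR-34 and p53 (1), miR-221 and miR-222 (2), skeletal muscle (0), the miR-183 cluster (0) and the 19q13 cluster (0). miR-221-3p had 0.22 (SE 0.30), miR-222-3p 0.08 (SE 0.33) and miR-34a-5p 0.08 (SE 0.33). Camera's preset correlation gave 5 calls among 14 lists, an estimated correlation 0, with 3 at an unadjusted p under 0.05, and fry also 0, with 3 at an unadjusted p under 0.05. In the 5 called lists the estimated correlation ran from 0.13 (myeloid) to 0.89 (melanocyte lineage), against the preset of 0.01.

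**Figure D3:**
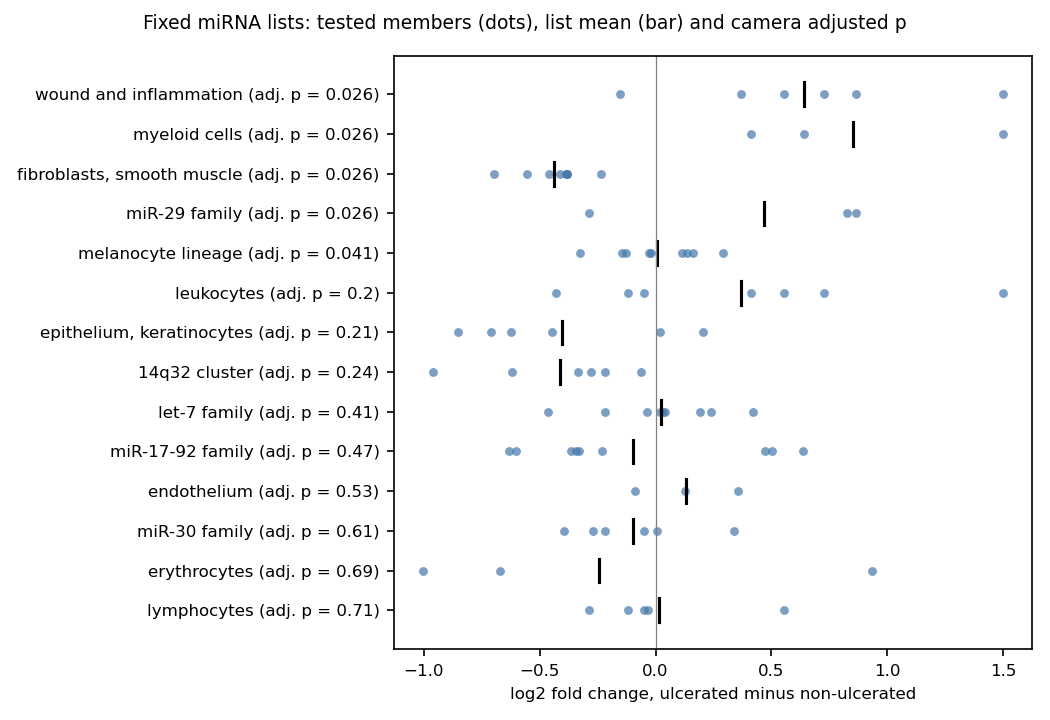
Log2 fold change, ulcerated minus non-ulcerated, of the tested members (dots) of 14 miRNA lists on the horizontal axis, with the list mean as a black bar and camera's adjusted p with the preset correlation beside each name. All 8 fibroblast and smooth muscle miRNAs lie below 0, and the melanocyte lineage mean is 0.01.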

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

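The tests on miR-4286, miR-223-3p, miR-196b-5p and miR-218-5p in this part were chosen after the result was seen, those on leukocytes, late-numbered miRNAs, the interaction with control level and background in place of earlier tests or rules, while the rule for the splits of the samples was set before their result was known, those within control levels having been added last. The library that stood under both groups entered no comparison, and 209 of its miRNAs lay above background. Its group remains unknown.

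Of 100 splits of the 33 samples into groups of 18 and 15, the real one included, 3 gave at least the 3 calls. This share is under the 0.05 level for splits that ignore the control level. However, 100 splits estimate it coarsely, so chance is not firmly excluded. With the control level as a block and splits made within the levels, 6 of 100 gave at least the 2 calls left, with 7 in the highest other split, so there chance could not be excluded. The highest of the other splits without the block gave 12 calls, several times the real count. It was picked for that count, and whether a structure of the samples lies behind it was not tested. That split explained 25.5% of the first principal component and was not tied to the control level (Fisher's exact test, p = 0.630), and 7 of its 12 calls were lower miRNAs numbered above 1200. For the lists chance could not be excluded, since 5 of 100 splits gave at least the 5 lists of the real grouping. The other splits had a median of 2 lists past the threshold and a highest count of 9, and 15 of them had 0. Camera's adjusted p at the preset correlation therefore understates how often lists pass by chance in these samples.

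miR-4286 was lower in ulcerated melanoma. An unequal mix of assay runs is argued against as the whole cause, because within the 8 samples of the high control level the log2 fold change was -3.99 (edgeR adjusted p = 0.00282). Within the low level it was -0.01, and with the level as a block it was -1.37 and the call was lost (edgeR adjusted p = 0.389). Whether the fall of miR-4286 had an equal size at all control levels could not be told, since the interaction given below did not pass over all miRNAs. Its confidence interval from edgeR ran from -1.32 to 1.29 at the low level. At the high level it ran from -5.12 to -2.86, without overlap, but miR-4286 was picked for its fall. The interval at the middle level, from -4.19 to -0.34, overlapped both. The interaction of group and control level had p = 0.00256 in edgeR for miR-4286, but an adjusted p = 0.425 over 166 miRNAs. Of these miRNAs, 4 had an unadjusted p under 0.05 where 8.3 would be reached by chance. A smaller fall of miR-4286 at the low level is not excluded by its interval there. A fall of late-numbered miRNAs as a whole, a class that is known to hold fragments of other RNAs, was not settled as a cause, because miR-4286 was picked for its fall. Of the 15 other tested miRNAs numbered above 1200, 12 were negative, with a median of -0.29 (SD 0.43) over the 15. Over all samples none lay below -1.31, so in that fit a fall of the size of miR-4286 was not seen across the class. By control level, miR-4488 of this class had -0.34, -0.93 and -2.44 at the low, middle and high level. For miR-1285-5p the values were -1.004, 0.60 and -1.53. These miRNAs were picked for their small p over all samples, and the other members were not compared by level. Whether the class fell at the high level was therefore not tested. The class had a camera p of 0.0149 at the preset and 0.282 at an estimated correlation. A biological difference tied to ulceration stays open and was not tested separately.

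miR-223-3p was higher in ulcerated melanoma without passing the threshold. More leukocytes of every kind would raise leukocyte miRNAs alike, and within samples miR-223-3p shifted by 1.13 (log2) over the mean of the 6 other tested leukocyte miRNAs, but it was picked for its rise. With each of the 7 in turn set against the others, the largest t had a permutation p of 0.0691 (miR-146b-5p, shifted by -0.69) and that of miR-223-3p a p of 0.113, so this explanation cannot be told apart from a change of miR-223-3p on 33 samples. An unequal mix of runs is argued against by a log2 fold change of 1.46 with the control level as a block (SE 0.49). A higher share of granulocytes or monocytes may account for the rise too and was not tested separately.

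miR-196b-5p was higher and miR-218-5p lower, both near background. The mean of the negative controls, scaled like the miRNAs, differed by -0.46 (log2, ulcerated minus non-ulcerated), with a 95% bootstrap interval from -1.08 to 0.12, and on a miRNA with no change of its own background makes a log2 fold change no larger than its own difference. This argues against background for miR-196b-5p, whose interval runs from 0.80 to 2.39, while that of miR-218-5p, from -1.92 to -0.75, overlaps. With background subtracted miR-218-5p stayed past the threshold (-1.77, SE 0.46, edgeR adjusted p = 0.0377), which argues against background as its whole cause, and the call of miR-196b-5p ended (2.62, edgeR adjusted p = 0.0978) because its SE grew from 0.39 to 0.77. With the control level as a block the smaller ratio of the 2 changes to their size without it was 0.93, which argues against an unequal mix of runs. This ratio does not test a difference between levels, and miR-218-5p had -1.16, -0.18 and -2.45 at the low, middle and high level.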

How the results depend on the processing

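Settings on the shared library, control level, background, dominant probe, voom without a block and single samples were chosen after seeing the data; the others were planned. Beside the 3 calls, no filter gave 7 (2 shared), a mean count of at least 100 gave 3 (miR-4286 shared, beside miR-206 and miR-29a-3p), sample quality weights 6, all 35 columns 5, the low, middle and high control level alone 0, 1 and 1, and the Wilcoxon test 0. Beside the 5 lists among 14, no filter gave 7 of 20 (4 shared), a mean count of at least 100 gave 2, quality weights 1, all 35 columns 3, the shared library as ulcerated 3, the high level alone 3, an estimated correlation 0 and fry 0. The middle level alone turned the mean of the melanocyte list to -0.61, of the myeloid list to -0.16 and of the wound list to -0.11. The melanocyte mean was below 0 in other fits too, among them the low level alone at -0.22. Fewer samples or miRNAs may explain part of these differences, but no cause was tested. Leaving out each of the 33 samples gave 3 to 5 calls and 2 to 5 lists, and miR-218-5p, miR-4286 and miR-196b-5p passed in all 33 fits. Over the refitted count or voom models other than single control levels, miR-218-5p passed in 13 of 14 (-1.77 to -1.12, adjusted p 0.000355 to 0.151), miR-196b-5p in 13 of 14 (1.30 to 2.62, 0.000369 to 0.0978) and miR-4286 in 12 of 15 (-2.49 to -1.37, 0.000369 to 0.389); miR-29a-3p passed in 5 of 15 and miR-223-3p in 3 of 15. The Wilcoxon test gave adjusted p 0.0641, 0.0861 and 0.533 for miR-218-5p, miR-196b-5p and miR-4286. Of values for named miRNAs, 1038 kept sign and side of the threshold, 11 gained a call, 13 lost one, 132 uncalled ones changed sign and 0 called ones did. Only the 3 called among 67 named miRNAs could lose a call, so most of the 1038 values belong to miRNAs uncalled in both fits. Whether patient numbers shared by the groups pair the samples stayed open. The 4 numbers gave correlations from -0.47 to 0.50, 3 of them above 0.1, against a median of 9.5e-04 for unlike numbers. Of these 4, 2 had both samples in the same control level, and 0 correlated best with their own number. As a replicate block the number had a consensus correlation of 0.16. With the number as a replicate block 3 miRNAs passed, miR-29a-3p in place of miR-4286, as in limma-voom without the block, and 5 lists. Log scale pseudocounts and quantile normalization do not apply to raw counts and were not run. Depth limits miRNAs near background: miR-218-5p and miR-196b-5p averaged 70.8 and 65.9 counts, against a mean background of 36.9 (median 24.8).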

Other observations

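Only the tests of chromosome 7 copies and of skeletal muscle below were written down before their result was seen; the other tests in this part were chosen afterwards. Without the filter on background, 3 of 6 miRNAs of skeletal muscle passed as lower in ulcerated lesions. miR-206 had a log2 fold change of -4.16 (SE 0.69, edgeR adjusted p = 0.000162), miR-1-3p -3.97 (SE 0.67, edgeR adjusted p = 0.000162) and miR-133a-3p -2.48 (SE 0.49, edgeR adjusted p = 0.0020). With a mean count of at least 100 as the filter miR-206 passed too, at -4.95 (edgeR adjusted p = 0.000658). The other 3, miR-133b at -0.33, miR-208b-3p at -0.36 and miR-499a-5p at -0.22, did not pass. Of these, miR-133b exceeded background in 0 ulcerated and 0 non-ulcerated samples, miR-208b-3p in 1 and 3, and miR-499a-5p in 1 and 0. The 3 that passed rest on few samples: miR-1-3p exceeded background in 0 ulcerated and 4 non-ulcerated samples, miR-206 in 1 and 4, and miR-133a-3p in 3 and 5. All 4 samples with miR-1-3p also had miR-206 (one-sided Fisher's exact test, p = 1.22e-04) and miR-133a-3p (p = 0.00171), which is consistent with some skeletal muscle in those biopsies. The list of 6 muscle miRNAs had a camera adjusted p of 1.44e-04 and an adjusted p = 0.177 with an estimated correlation.

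How often a miRNA was seen at all did not differ past the threshold for any of 149 miRNAs (two-sided Fisher's exact tests), 9 of which had an unadjusted p under 0.05. Those of smallest p follow. miR-135b-5p exceeded background in 13 of 18 ulcerated and 2 of 15 non-ulcerated samples, miR-1973 in 1 and 9, and miR-4284 in 3 and 11, each with an adjusted p of 0.0799. miR-135b-5p was 1 sample short of the filter, and it passed without the filter at a log2 fold change of 1.83 (edgeR adjusted p = 0.00863) and over all 35 columns at 1.27 (edgeR adjusted p = 0.0415). miR-489-3p also passed without the filter, as lower, at -3.74 (edgeR adjusted p = 0.0020). It exceeded background in 4 of 18 ulcerated and 7 of 15 non-ulcerated samples.

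All 6 tested miRNAs with genes on chromosome 7 alone had positive fold changes, from 0.47 to 1.59: miR-106b-5p, miR-93-5p, miR-25-3p, miR-148a-3p, miR-29a-3p and miR-196b-5p. Only miRNAs past the filter on background were placed on chromosomes, so those below it, such as miR-489-3p, did not enter. Among 19 chromosomes this set had the smallest camera p (adjusted p = 3.45e-06, and adjusted p = 0.0236 with an estimated correlation), but the set was noticed in these data. A gain of chromosome 7 copies in ulcerated tumours is a candidate explanation. It would make the 4 separate loci vary together among samples of a group, and their mean pairwise correlation of 0.13 lay at the percentile 85.7 of 10000 random sets of 4 other miRNAs, below the 95th percentile of 0.22 and above the median of -0.01. This test leaves the hypothesis undecided.

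A pair of contrasts was formed from members already seen to go opposite ways, so these are values and no independent test. Within samples the mean of 3 miR-106b-25 members relative to 6 miR-17-92 probes was 0.53 higher (log2) in ulcerated lesions, with 0.41, 0.95 and 0.53 at the low, middle and high control level. The mean of miR-29a-3p and miR-29b-3p relative to miR-29c-3p was 1.16 higher, with 1.34, 1.18 and 0.76 by level.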
